A study of Mus musculus with 6 samples.

How the data were processed

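Omni-ATAC-seq was carried out on GFP-positive lung fibroblasts of Col1a1-GFP transgenic mice. Per the labels, cells were seeded at 5000 per cm2 on surfaces coated with collagen I at 0.1 mg per mL, grown in medium with 10% serum and harvested after 8 days. Each library used 50000 cells and was read to 51 bp from both ends. Samples were grouped by the culture named in their labels (0.2 kPa PDMS, 32 kPa PDMS or plastic), with 2 libraries per culture.

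The submitters' processing notes name BWA, Picard, MACS2 and DiffBind, with no versions or settings, and the build mm10. Whether reads were shifted for the transposase, how peaks were merged and how libraries were scaled is not given in the sources used here. Each of the 3 deposited tables compares a pair of cultures region by region. Per the file headers, the deposited concentrations and folds follow the layout of a DiffBind report: a log2 mean of normalised reads over the libraries of a culture, and a log2 fold that is the difference of those means. The deposited p-value and FDR are the authors', computed across the regions they tested. Gene names, distances to the nearest TSS and annotations were those in the deposited tables, in the layout of HOMER, and were used as given. Distances are signed bases relative to the gene's strand, with negative values upstream. Because a region is given the gene of its nearest TSS, it may act on another gene, or on none. At regions matched between tables by at least 90% of both lengths, the gene name differed at 35 of 1764 and 35 of 1727 regions. No table gave values per library, and depth per library is unknown, so no counting interval can be given and precision rests on the authors' FDR alone. No column belonged to another study, and 1 repeated header row was dropped from the table of 32 kPa against plastic.

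The tables of 0.2 kPa call their sides Control and Treat. They were identified from the values at intervals that also occur in the table of 32 kPa against plastic, whose columns name the cultures. At 643 such intervals the Control level equalled the 32 kPa level at each one, and at 653 intervals of the plastic comparison it lay 0.01 to 0.02 above the plastic level. Control was therefore read as the stiffer culture and Treat as 0.2 kPa, and a positive fold as more accessible on the stiffer culture. In both tables every fold was at least 1 and every FDR at most 0.05. In the 32 kPa comparison region identifiers ran to 5480 in order of p-value, of which 2121 were listed.

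Overlap between lists was counted with bedtools 2.31.1 at a minimum of 1 bp. Levels on the culture absent from a comparison were read from the table of 32 kPa against plastic at the region sharing at least 50% of both lengths. The background for location and gene lists was the regions of that table that overlapped no listed region and reached the lowest listed level on the same stiffer culture, 14904 regions for 32 kPa and 15892 for plastic. The background regions have no level on 0.2 kPa in the tables used here. They can therefore include regions that changed by a fold below 1, or in the opposite direction. Odds ratios are conditional, with exact 95% intervals and two-sided Fisher's exact tests, and Benjamini-Hochberg adjustment was over 16 lists per comparison or over 16 location tests. These tests count regions, which are not independent replicates. Odds ratios at equal level are Mantel-Haenszel estimates over 10 strata of the level on the stiffer culture, an addition made after seeing the data. The same estimate between the lists was set after that, before its own result was seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

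The overlap with shared libraries was simulated 1000 times, with unchanged regions, equal error in each culture and lists of the observed lengths. The same simulation, with folds scaled so that the lowest listed was 1, gave the share of regions of a single list at least 0.5 higher on the other stiffer culture. In the comparison of 32 kPa with plastic, each list's median fold was placed among 10000 random region lists matched on level and promoter location, and among 2000 random gene lists matched on the number of regions, the latter added after the first percentiles were seen. The stratified odds ratio was tested on simulated data of 16000 regions and recovered 1.02, 2.06 and 4.21 for planted odds ratios of 1, 2 and 4, against 1.82, 3.60 and 7.24 without strata. The simulated regions were not selected on a fold that holds the level of the strata, as the listed regions were. The test therefore does not cover a bias from that selection.

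Before the data were examined, 16 gene lists were fixed: fibrillar collagen and matrix; actin, contractile and myofibroblast; YAP/TAZ-TEAD targets; TGF-beta pathway; integrins and focal adhesion; alveolar and lipid fibroblast; adventitial and universal fibroblast; antifibrotic prostaglandin, cAMP and growth factor; inflammatory and NF-kappaB; AP-1, RUNX and other mechano-responsive transcription factors; proteases; cell cycle; and markers of epithelial, endothelial, leukocyte, and pericyte, smooth muscle and mesothelial cells. A region counted for a list when its gene was a member and its TSS lay within 100 kb. A gene was measured when it had a listed or background region within that distance. The rule for named genes, fixed at the same time, took per comparison and direction the 6 genes with the largest fold and the 3 with the most called regions (ties by FDR), and up to 4 genes per list with the lowest FDR. It always took a fixed set of genes, of which those described here are Acta2, Col1a1, Col1a2, Col3a1, Fn1, Ccn1, Ccn2, Ankrd1, Tagln, Runx1, Runx2, Tcf21, Pparg, Hgf and Ptgs2. Each gene was described by its region of lowest FDR. For 32 kPa against plastic every FDR was 1 and the region of lowest p was taken, and the region of highest level is given beside it. Other list members are named only where a count is spelled out, chosen after their values were seen. Tests on values per library had been intended, and the authors' calls were used in their place. Motif searches, fits per library and a test of replicate pairing were not carried out, since no genome sequence and no values per library were used here. Alternatives tried were an FDR under 0.01, other distance windows, a reciprocal overlap of 50%, the upper part of regions by level, median-centred folds and a background of all regions.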

Results

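Open chromatin was profiled by Omni-ATAC-seq, in which a transposase cuts and tags accessible DNA, in primary mouse lung fibroblasts. The cells were GFP-positive fibroblasts sorted from the lungs of Col1a1-GFP transgenic mice. They were grown for 8 days on surfaces coated with collagen I, either 0.2 kPa silicone (PDMS), 32 kPa PDMS or tissue-culture plastic. Each of the 3 cultures had 2 libraries of 50000 cells, 6 libraries in all. The comparisons asked which regions of the genome differed in accessibility between the soft surface and the stiffer ones, and whether 32 kPa PDMS and plastic differed from each other. Values are the authors' mean level per region and culture, in log2 normalised reads, and folds are differences of those log2 means. The tables used here hold 1 mean per culture, so the spread between libraries and the sequencing depth are unknown. Whether the libraries of a culture came from separate animals is not given in the sources used here, and the authors' p-values then measure only the spread between these libraries, which may be technical.

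Fibroblasts on 32 kPa PDMS had 2121 regions more accessible than on 0.2 kPa PDMS in the authors' deposited table. These included the promoters of the smooth muscle actin gene Acta2, the actin-bundling gene Tagln, the non-muscle myosin gene Myh9, the collagen crosslinking enzyme gene Lox and the TGF-beta receptor gene Tgfbr1. A region in the 5' UTR of Ctgf (Ccn2), a matricellular gene regulated by YAP and TAZ, was also among them. The median fold was 1.12 on the log2 scale, a 2.17-fold difference, with an interquartile range across regions of 1.05 to 1.22 and a maximum of 2.11. The table listed no region that was higher on 0.2 kPa, no fold below 1 and no FDR above 0.05. Regions that changed less, or in the opposite direction, were therefore not analysed as changes here. Identifiers in order of p-value ran to 5480, so 3359 further regions may have passed the same FDR without being listed. Regions left out can fall among the other regions with which listed regions are compared below.

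The largest folds lay near genes outside the fixed lists, and mostly far from their start sites. These were weak regions on 0.2 kPa, at levels of 3.24 to 3.56 against a median of 4.83 over the listed regions. A region on chromosome 11 (15765026 to 15765300, mm10), 493 kb upstream of Vstm2a, rose from 3.24 on 0.2 kPa to 5.35 on 32 kPa in the authors' deposited table (fold 2.11, FDR = 0.00225). It was followed in the authors' deposited table by an intergenic region 63.9 kb upstream of Nt5c1b (fold 2.07) and by an exon of the neighbouring gene Fnip1, 20.1 kb upstream of Rapgef6 (fold 1.97). The next were an intron at 4930556M19Rik (fold 1.88), an intergenic region whose nearest gene was 1700054K19Rik (fold 1.87) and the 3' end of Lingo4 (fold 1.85), also from the authors' deposited table. Atp10a, a phospholipid-transporting ATPase gene, had 4 listed regions with folds of 1.04 to 1.29 in the authors' deposited table. Ube2u and Ism1 had 3 each, with folds of 1.02 to 1.45 and of 1.16 to 1.56 in the authors' deposited table. Those assigned to Ube2u lay 92 to 167 kb upstream of it, in introns of a neighbouring transcript.

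Contractile and cytoskeletal genes gave the largest number of genes with regions listed as higher on 32 kPa among the fixed lists. Of 30 genes of the actin, contractile and myofibroblast list with a region high enough to be listed, 14 had at least 1 listed region. The other 16 had none, which leaves smaller rises possible. The Myh9 promoter (chromosome 15, 77842061 to 77842785) rose from 7.15 to 8.18 in the authors' deposited table (fold 1.04, FDR = 0.000818). The Actn1 promoter rose by 1.19 (FDR = 0.00154), a region 14.2 kb upstream of Actb by 1.23 (FDR = 0.00129) and the Cnn3 promoter by 1.01 (FDR = 0.00597), per the authors' deposited table. The Acta2 promoter (chromosome 19, 34255198 to 34255703) rose from 5.37 to 6.49 in the authors' deposited table (fold 1.12, FDR = 0.00698). At the Tagln promoter (chromosome 9, 45935852 to 45936208) the level went from 5.15 to 6.34 in the authors' deposited table (fold 1.18, FDR = 0.0117). The list made up 0.754% of the listed regions and 0.396% of the other regions at or above the lowest listed level, an odds ratio of 1.91 (exact 95% interval 1.03 to 3.38, Fisher's exact test p = 0.033, adjusted p = 0.26 over 16 lists).

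Collagen and matrix genes gave 12 of 31 measured genes with a listed region on 32 kPa (odds ratio of regions 1.47, exact 95% interval 0.762 to 2.65, Fisher's exact test adjusted p = 0.72). A region 7.09 kb upstream of Serpinh1, which encodes the collagen chaperone HSP47, rose from 6.37 to 7.63 in the authors' deposited table (fold 1.26, FDR = 0.000419). The Lox promoter (chromosome 18, 52529435 to 52530113) rose by 1.09, the 5' UTR of Sparc by 1.25 and a region 9.95 kb upstream of Fbln2 by 1.20, per the authors' deposited table. Of the fibrillar collagen I genes, Col1a2 had 2 listed regions, led by an intergenic one 15.5 kb upstream of the gene (chromosome 6, 4489989 to 4490288, fold 1.27, FDR = 0.0111 in the authors' deposited table). Col1a1, Col3a1 and Fn1 had none in this comparison. The strongest Col3a1 region (4.71 on 32 kPa) and the Fn1 region (3.90) lay below the lowest listed level of 4.97. Absence from the list is therefore no evidence about a change at these 2 genes.

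Among YAP/TAZ-TEAD target genes, 10 of 29 measured genes had a listed region on 32 kPa (odds ratio of regions 1.36, exact 95% interval 0.667 to 2.56, Fisher's exact test adjusted p = 0.77). With genes assigned within 10 kb it was 0.413, so its direction depended on the window. The Ctgf region (chromosome 10, 24595341 to 24595935) rose from 5.74 to 6.79 in the authors' deposited table (fold 1.05, FDR = 0.00721). Regions at Myof, Vgll3 and Nuak2 rose by 1.14, 1.21 and 1.10 in the authors' deposited table. Ccn1 and Ankrd1, other targets of the pathway, had no listed region. The TGF-beta list had 7 of 29 genes with a listed region, among them the promoters of Skil (fold 1.18, FDR = 0.000751) and Tgfbr1 (fold 1.11, FDR = 0.00154) in the authors' deposited table. Of integrin and focal adhesion genes, 2 of 28 had a listed region, Itgb8 and Tns1 (odds ratio 0.209, exact 95% interval 0.0248 to 0.786, Fisher's exact test p = 0.0099, adjusted p = 0.16), and 0.668 when gene bodies and flanks were used. The AP-1, RUNX and other transcription factor list had 7 of 34 genes, led by the Fosl2 promoter (fold 1.06, FDR = 0.000888 in the authors' deposited table), and Runx2 was listed with a fold of 1.06 at an intron. Runx1 was not listed.

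Regions near genes of the alveolar, adventitial and antifibrotic fibroblast lists also rose on 32 kPa, in small numbers. They were Cd36 and Cebpd of the alveolar and lipid list (2 of 16 genes), Twist1 and Sfrp1 of the adventitial list (2 of 16), and Fgf2, Fgf7 and Thy1 of the antifibrotic list (3 of 17). Fgf7, a fibroblast growth factor for epithelial cells, rose by 1.45 at an intron in the authors' deposited table (chromosome 2, 126060675 to 126060955, FDR = 0.00927). Tcf21, Pparg, Hgf and Ptgs2 had no listed region. The strongest regions of Tcf21 and Pparg, at 4.88 and 4.94 on 32 kPa, were below the lowest listed level of 4.97 and could not be listed. The inflammatory list had 5 of 21 genes with a listed region (Il1rl1, Il1r1, Lif, Ptx3 and Ccl20), the protease list 6 of 22 (Adamts15 leading, fold 1.45 in the authors' deposited table) and the cell cycle list 4 of 32 (Pcna, Ccne1, Rb1 and Ccnd3). Of markers of other cell types, 1 of 11 epithelial genes (Hopx) had a listed region, against 0 of 8 endothelial and 0 of 4 leukocyte genes, and of pericyte, smooth muscle and mesothelial genes 2 of 8 (Wt1 and Upk3b). The last of these lists had the highest odds ratio of regions in both comparisons, 2.64 here (exact 95% interval 0.45 to 11) and 3.22 on plastic (0.538 to 14.1), from 3 listed regions each. These values depended on the setting. Within 10 kb they were 0 here and 7.52 on plastic, and with an FDR under 0.01 they were 5.38 and 0. Regions nearest Upk3b and Wt1, which mark mesothelium, rose by 1.57 and 1.43 in the authors' deposited table. That of Upk3b lay 18.4 kb upstream of the gene. None of the 16 lists passed adjustment over the lists in this comparison.

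Fibroblasts on plastic had 2114 regions more accessible than on 0.2 kPa PDMS, again with no listed region in the opposite direction, in the authors' deposited table. The promoters of Acta2, Tagln and Actn1 rose here too, as did regions at Col1a2, Sparc, Vgll3 and Fgf7. Col1a1 and Eln, the elastin gene, were listed in addition. The leading regions of Eln and Col1a1 were also 1.21 and 0.86 higher on 32 kPa than on 0.2 kPa, so their listing does not separate the 2 stiffer cultures. The median fold was 1.12, the interquartile range across regions 1.05 to 1.22 and the maximum 1.85 in the authors' deposited table. The largest folds lay at regions near Gm15694 (1.85), Gm5796 (1.79), Gabra4 (1.76), Ms4a1 (1.73), Unc13c (1.73) and Lyzl1 (1.72) in the authors' deposited table. Their levels on 0.2 kPa were 3.25 to 4.40, below the median of 4.61 over the listed regions. Malat1, a nuclear long noncoding RNA gene, had 4 listed regions 7.67 to 15.5 kb upstream, with folds of 1.03 to 1.20 in the authors' deposited table. Rpl31 had 4 as well, of which 1 was its promoter (fold 1.15) and 3 lay in introns of a neighbouring transcript, and Foxp1 had 3 (folds 1.21 to 1.28) in the authors' deposited table.

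On plastic, 10 of 31 collagen and matrix genes had a listed region (odds ratio of regions 1.68, exact 95% interval 0.908 to 2.92, Fisher's exact test p = 0.067, adjusted p = 0.36). A region 16.3 kb upstream of Eln rose from 3.95 to 5.49 in the authors' deposited table (chromosome 5, 134763393 to 134763769, fold 1.55, FDR = 0.00581). The intergenic region upstream of Col1a2 rose by 1.32 (FDR = 0.00379) and an intron of the crosslinking enzyme gene Loxl1 by 1 (FDR = 0.00328) in the authors' deposited table. Col1a1 had 2 listed regions, led by one 2.46 kb upstream of the gene (chromosome 11, 94933610 to 94933927, fold 1.03, FDR = 0.013 in the authors' deposited table). Col3a1 and Fn1 were not listed, but their strongest regions (4.90 and 3.95 on plastic) were below the lowest listed level of 4.94. Contractile genes had 10 of 33 measured genes with a listed region (odds ratio of regions 1.22, exact 95% interval 0.602 to 2.27, Fisher's exact test adjusted p = 0.73), with 0.98 within 10 kb and 2.5 with an FDR under 0.01. The Acta2 promoter rose from 5.38 to 6.60 (fold 1.22, FDR = 0.000817) and the Tagln promoter from 5.10 to 6.36 (fold 1.26, FDR = 0.00177) in the authors' deposited table. Actn1 and Actn4 rose by 1.15 and 1.24 in the authors' deposited table.

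Of YAP/TAZ-TEAD target genes, 3 of 27 had a listed region on plastic, namely Vgll3 (fold 1.37), Tgfb2 (1.40) and Yap1 (1.31) in the authors' deposited table. The odds ratio of regions was 0.331 (exact 95% interval 0.0665 to 1.01, Fisher's exact test p = 0.061, adjusted p = 0.36). The regions of this list numbered 12 in the 32 kPa list and 3 in the plastic list, and the difference between the lists did not pass adjustment (odds ratio 4, exact 95% interval 1.08 to 22.1, Fisher's exact test p = 0.035, adjusted p = 0.48). Ccn1, Ccn2 and Ankrd1 were not listed on plastic. The regions listed for 32 kPa at Ctgf (Ccn2), Myof and Nuak2 were still 0.87, 0.89 and 0.99 higher on plastic than on 0.2 kPa, short of a fold of 1. These differences use the 0.2 kPa level on which the regions were selected. The AP-1, RUNX and other transcription factor list had 2 of 35 genes, Id3 (fold 1.05) and Runx2 (1.24 in the authors' deposited table), with an odds ratio of 0.18 (exact 95% interval 0.0215 to 0.673, Fisher's exact test p = 0.0035, adjusted p = 0.056), and of 0.306 (Fisher's exact test adjusted p = 0.49) within 10 kb. Its regions numbered 9 in the 32 kPa list and 2 in the plastic list (odds ratio 4.50, exact 95% interval 0.93 to 42.8, Fisher's exact test adjusted p = 0.48).

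The TGF-beta list had 6 of 29 genes listed on plastic, including the Smad3 promoter (fold 1.01, FDR = 0.00509 in the authors' deposited table), and the integrin list 7 of 29 (Itgav, Itgb5, Ptk2, Itga8, Itga2, Itgb1 and Piezo2). The antifibrotic list had 4 of 17 genes, with Fgf2, Gucy1b1, Fgf7 and Ptger4 at folds of 1.01 to 1.41 in the authors' deposited table. Single genes were listed from the alveolar list (Rarb, 1 of 17, fold 1.08 at its promoter) and the adventitial list (Serpinf1, 1 of 18, fold 1.07), per the authors' deposited table. The inflammatory list had 2 of 21 genes (Tnfaip3 and Lif), the protease list 5 of 20 (Adamts5, Adamts15, Timp3, Mmp23 and Adam12) and the cell cycle list 3 of 34 (Ccnd2, Rb1 and Cdk6). Of other cell types, 3 of 10 epithelial genes (Hopx, Krt19 and Krt8), 3 of 11 endothelial genes (Emcn, Kdr and Sox18) and 3 of 7 pericyte, smooth muscle and mesothelial genes (Wt1, Krt19 and Myh11) had listed regions, against 0 of 3 leukocyte genes. None of the 16 lists passed adjustment in this comparison either.

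**Figure D1:**
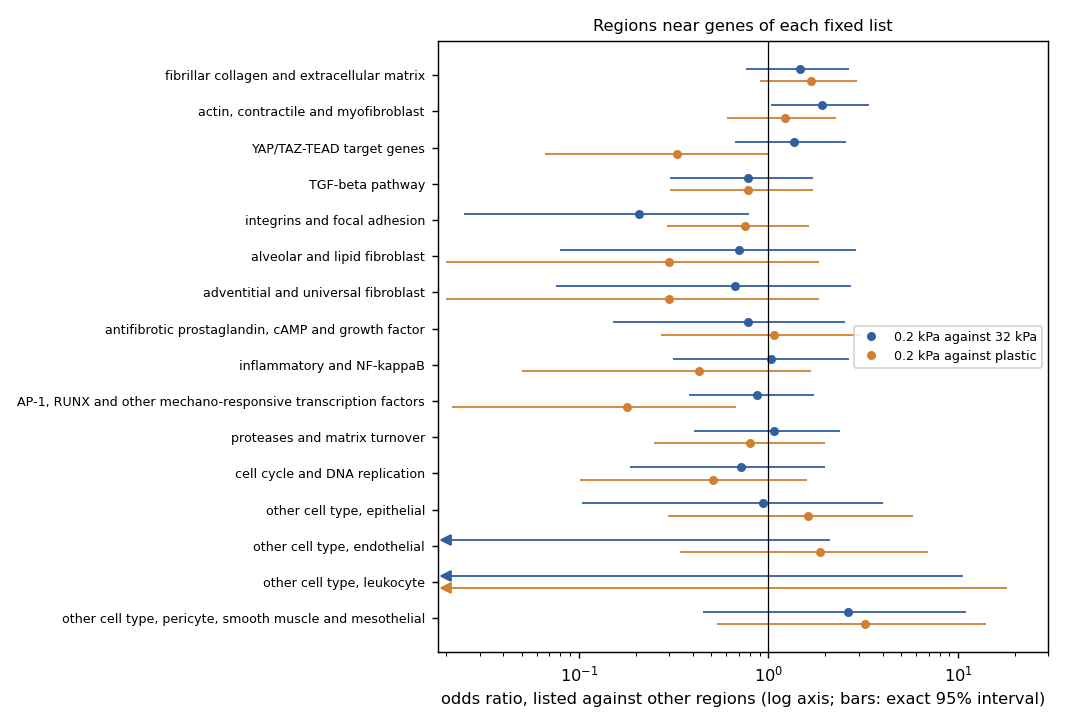
Odds ratio (log axis) that a region listed as higher on 32 kPa (blue) or plastic (orange) than on 0.2 kPa lay near a gene of each fixed list, relative to other regions at or above the lowest listed level; bars are exact 95% intervals, bars at the left edge continue beyond it, and arrowheads mark lists with 0 listed regions. The contractile list on 32 kPa had 1.91 and the transcription factor list on plastic 0.18, and no list passed adjustment over 16 lists.

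The soft surface was common to both comparisons, and the same regions recurred in part. Of the 2121 regions higher on 32 kPa, 680 (32.1%) overlapped a region higher on plastic by at least 1 bp. Genes with listed regions in both comparisons included Acta2, Tagln, Actn1, Actn4, Myh9, Myl9 and Tpm2 of the contractile list, Col1a2, Col5a1, Fbln2, Sparc and Vcan of the matrix list, and Fgf2 and Fgf7 of the antifibrotic list. Among 15631 regions high enough for both lists, 680 were in both, against 219 for independent lists of these lengths (odds ratio 6.26, exact 95% interval 5.59 to 7.01, Fisher's exact test p = 5.2e-203). Both lists share the 0.2 kPa libraries. Simulated unchanged cultures with that sharing gave 643 (95% range 608 to 679), and the 680 observed lay just above that range. The simulation gave every region the same error. In the data the listed share varied with level, from 6.65% to 21% of regions across levels for 32 kPa. The simulated range therefore cannot decide how much of the overlap comes from the shared libraries. The shared libraries could not be split between the comparisons because the tables hold means.

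Regions in the 32 kPa list alone were nearly all higher on plastic too. At 1439 such regions the level on plastic exceeded that on 0.2 kPa by a median of 0.86 (interquartile range 0.74 to 0.95), and 13.5% reached 1. At 1427 regions in the plastic list alone the level on 32 kPa exceeded that on 0.2 kPa by a median of 0.84 (interquartile range 0.71 to 0.95), and 16.3% reached 1. Of 2117 regions in the 32 kPa list with a plastic value, 2115 were above the 0.2 kPa level, and of 2102 regions in the plastic list 2099 were higher on 32 kPa. These differences use the 0.2 kPa value on which the region was selected, and simulated unchanged cultures with equal error put 82.3% and 82.9% of listed regions above 0. That most regions of a single list lay below 1 on the other culture also follows from the selection. The region at Cd36 was 1 of the exceptions, with a fold of 1.23 on 32 kPa in the authors' deposited table and a plastic level 0.04 below that on 0.2 kPa (difference -0.04). At the promoters of Acta2 and Tagln the plastic level exceeded the 0.2 kPa level by 1.22 and 1.26, and at Ctgf by 0.87.

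**Figure D2:**
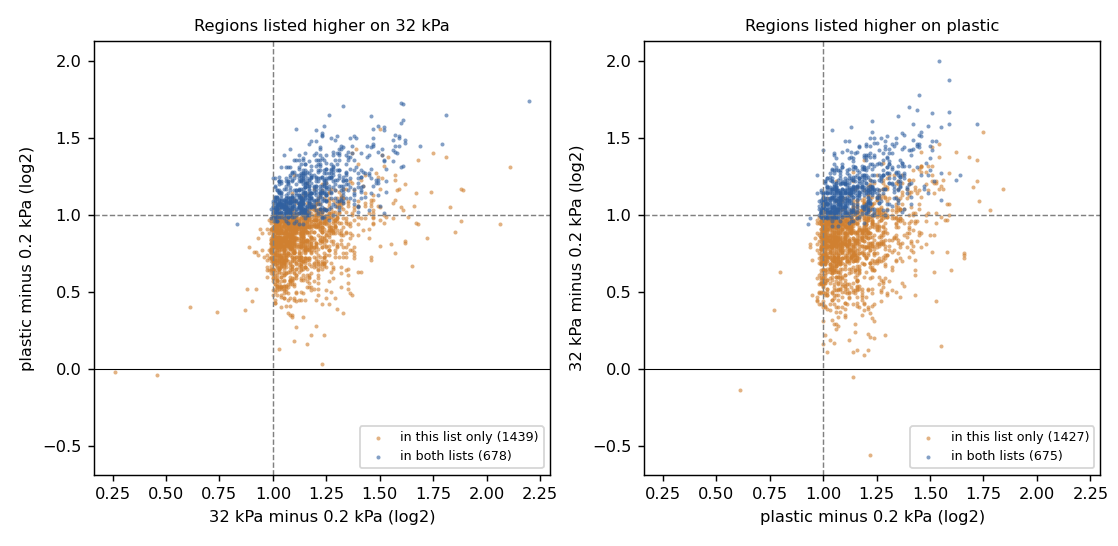
Difference from 0.2 kPa (log2) on 32 kPa and on plastic for each region listed as higher on 32 kPa (left) or on plastic (right); each point is a region, blue if it is in both lists and orange if in the list of that panel alone, and dashed lines mark a difference of 1. Orange points cluster below 1 for the other stiffer culture, with medians of 0.86 and 0.84, as the selection into a single list brings about.

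No region was called as different between 32 kPa PDMS and plastic, in a test with 2 libraries per culture and few small p-values. Of 64217 regions in the authors' deposited table, DiffBind called 0 at an FDR of 0.05, and every FDR was 1. An unadjusted p under 0.05 was given to 370 regions (0.576%), against 3211 for evenly spread p-values, and 245 of those were higher on plastic and 125 on 32 kPa. Region levels correlated across regions between the 2 cultures (Pearson's r = 0.915, regions not being independent replicates). The median difference, plastic minus 32 kPa, was 0.05 with an interquartile range across regions of -0.19 to 0.33. Differences of at least 1 occurred at 2089 regions toward plastic and 914 toward 32 kPa, at a median level of 8.46 reads against 18.4 reads for all regions.

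No region near a gene of fibroblast activation was called between these surfaces. By the fixed rule, which with every FDR at 1 takes the region of lowest p, most of these genes were described by weak regions. An intron of Acta2 had 3.36 on plastic and 4.33 on 32 kPa (difference -0.98), and regions at Ccn1 and Col1a2 differed by -1.96 and -0.51 in the authors' deposited table. Those at Runx1 (-0.85), Pparg (-0.84) and Tcf21 (-0.82) were also lower on plastic in the authors' deposited table. Regions assigned to Runx2 (1.74), Hgf (1.67), Ankrd1 (1.23), Ccn2 (0.86), Ptgs2 (0.63), Col1a1 (0.57) and Col3a1 (0.57) were higher on plastic in the authors' deposited table. Those of Runx2 and Hgf lay 181 and 169 kb from the gene's start. The promoter of Tagln (0.07) and the Fn1 region (0.05) were nearly equal.

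At the region of highest level, the differences were smaller except at Tagln and Fn1, where the region was the same, and 9 genes changed sign. The Ccn2 regions described here lay 102 and 148 kb upstream, and its promoter carries no gene name in this table. The Acta2 promoter had 6.59 on plastic and 6.49 on 32 kPa, and the Tagln promoter 6.41 and 6.34, in the authors' deposited table. The strongest regions of Col1a1 and Ptgs2 lay 0.19 and 0.14 higher on plastic, and those of Col1a2, Col3a1 and Pparg 0.07 to 0.19 higher, in the authors' deposited table. Those of Ankrd1 (-0.29), Ccn1 (-0.21), Runx2 (-0.09), Ccn2 (-0.05) and Hgf (-0.04) lay lower on plastic in the authors' deposited table. The promoters of Tcf21 and Runx1 were 0.39 and 0.15 higher on plastic in the authors' deposited table. The lowest p-value belonged to an intergenic region at -4015 bp from the start of Nfu1, at 5.17 on plastic and 3.39 on 32 kPa in the authors' deposited table (p = 0.000997).

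Of the fixed lists, inflammatory genes and YAP/TAZ-TEAD targets had the lowest medians. The median over 202 regions of 30 YAP/TAZ-TEAD target genes was -0.06 (interquartile range -0.28 to 0.23), at percentile 0.005 of 10000 random region lists matched on level and promoter location, whose median was 0.04. It was at percentile 0.95 of 2000 random gene lists matched on the number of regions. The inflammatory list, with 153 regions of 31 genes, had a median of -0.07, at percentile 0.065 of matched region lists and 0.925 of gene lists. The transcription factor list had -0.03, at percentile 0.62 of region lists and 38.5 of gene lists. The contractile list had 0.04 (percentile 50.3 of region lists and 95.9 of gene lists) and the collagen and matrix list 0.00 (5.88 and 56). The other 11 lists lay between percentiles 6.91 and 90.6 of region lists and 46 and 96.2 of gene lists, the highest of both being the adventitial list. Adjusted over the list alone, 0 regions were called in each of the 16 lists, as over all regions tested. These percentiles describe these libraries, since the tables hold no replicate values for a test of the lists.

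**Figure D3:**
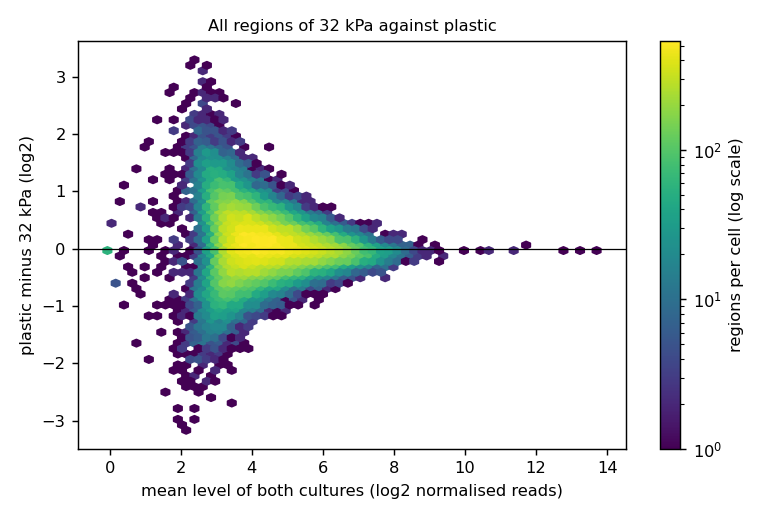
Difference between plastic and 32 kPa (log2, vertical) against the mean level of both cultures (log2 normalised reads, horizontal) for 64217 regions, with colour for the number of regions per cell (log scale). The spread narrows as the level rises, with a median difference of 0.05.

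Many listed regions lay at promoters. Within 1000 bp of a transcription start site (TSS) lay 1038 of the regions higher on 32 kPa (48.9%) and 893 of those higher on plastic (42.2%), as at Acta2, Tagln and Actn1. Among other regions of at least the lowest listed level the shares were 48.1% and 47.7%, giving odds ratios of 1.03 (exact 95% interval 0.942 to 1.13, Fisher's exact test p = 0.5) and 0.801 (0.73 to 0.878, p = 2e-06). The share of promoters rose with the level of a region, from 21.9% to 82.6% across levels of the 32 kPa list. Averaged over levels, listed regions were less often promoters than others of equal level, with Mantel-Haenszel odds ratios of 0.76 (95% interval 0.689 to 0.838) and 0.706 (0.64 to 0.779). That level is also the high side of the fold by which regions were listed. Since promoters were rarer at lower levels, selection on the fold can lower these odds ratios by itself. They therefore cannot show a difference in location. The lower share of promoters came mostly from regions below a level of 6.5. At levels of 7.5 and more, promoters were 82.6% of regions listed for 32 kPa and 79.2% of others, and 93.8% of regions listed for plastic and 78.1% of others. With an FDR under 0.01 the odds ratios without regard to level were 2.20 and 1.66. At equal level they were 0.889, which was not distinguishable from 1, and 0.828.

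Intergenic regions, LTR retrotransposons, and exons and UTRs differed for plastic. Introns held 26.4% of the regions higher on 32 kPa and 26.0% of others (odds ratio 1.02, Fisher's exact test p = 0.69), and only at equal level were they more frequent (Mantel-Haenszel odds ratio 1.24, 95% interval 1.12 to 1.38). Selection on the fold can raise that estimate, as introns were more frequent (37.6%) when lower regions were counted among the others. For plastic, the intergenic share was 29.7% against 26.0% (odds ratio 1.20, exact 95% interval 1.08 to 1.33, Fisher's exact test adjusted p = 0.0021 over 16 tests). LTR retrotransposons held 4.97% of the regions higher on plastic and 2.79% of other regions (odds ratio 1.82, exact 95% interval 1.45 to 2.27, Fisher's exact test adjusted p = 5.8e-06), and 2.83% of both kinds for 32 kPa. At equal level both excesses on plastic stayed, with Mantel-Haenszel odds ratios of 1.96 (95% interval 1.57 to 2.45) for LTR retrotransposons and 1.27 (1.14 to 1.40) for intergenic regions. Selection on the fold can raise these estimates too, since both features were more frequent among lower regions. Against all regions, most of them lower, the odds ratio was 0.923 for LTR retrotransposons (exact 95% interval 0.749 to 1.13) and 0.671 for intergenic regions. Exons and UTRs held 2.22% of the regions higher on plastic and 3.36% of others (odds ratio 0.654, Fisher's exact test adjusted p = 0.015), and the odds ratio against all regions was 0.682. Chromosome X held fewer listed regions than others, at 1.23% against 1.97% for 32 kPa (odds ratio 0.617, exact 95% interval 0.395 to 0.925, Fisher's exact test adjusted p = 0.043) and 0.946% against 1.90% for plastic (odds ratio 0.493, 0.296 to 0.777, adjusted p = 0.0048).

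**Figure D4:**
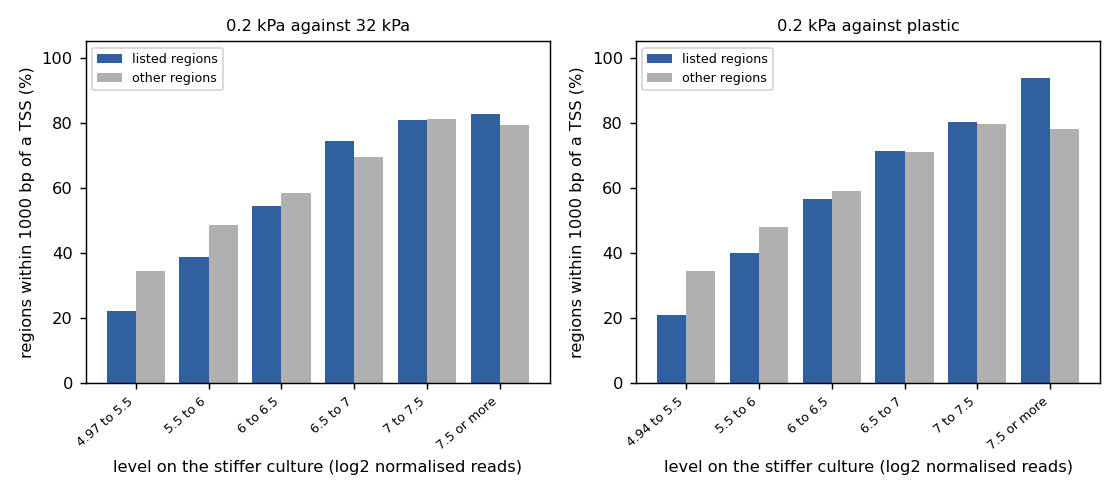
Percent of regions within 1000 bp of a TSS (bars, from 0) by the level on the stiffer culture in log2 normalised reads, for listed regions (blue) and other regions of at least the lowest listed level (grey), in both comparisons with 0.2 kPa. In the 32 kPa comparison listed regions were at 21.9% and others at 34.4% in the lowest bin, and at 82.6% and 79.2% in the highest.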

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

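The tests between the lists and of the median difference between surfaces were chosen after results were seen. The tests of one list against the other at equal level were set before their own results were seen, but after each list had been compared with its background at equal level.

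The regions listed as higher on 32 kPa and on plastic, both against 0.2 kPa, differed in where they lay by direct tests of one list against the other. Regions within 1000 bp of a TSS were 48.9% of the 32 kPa list and 42.2% of the plastic list (odds ratio 1.31, Fisher's exact test adjusted p = 0.00011 over 8 features). The level of the regions is a candidate explanation for the promoters, since at equal level on the stiffer culture the odds ratio was 0.98 (95% interval 0.857 to 1.12). A shift of all promoter regions by 0.05 or more is argued against for the means of these libraries alone. The 7842 promoter regions high enough for both lists differed from others by -0.02 in median plastic minus 32 kPa (bootstrap 95% interval over regions -0.04 to -0.02), and a smaller shift stays open. That interval holds no spread between libraries, so it cannot bound a shift between the surfaces themselves. The difference between 32 kPa PDMS and plastic as surfaces remains among the open explanations, as untested.

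LTR retrotransposons were 2.83% of the 32 kPa list and 4.97% of the plastic list (odds ratio 0.557, Fisher's exact test adjusted p = 0.00088). Region level argues against being the whole explanation, since the odds ratio at equal level was 0.659 (95% interval 0.476 to 0.913). A shift of all LTR regions stays open: 431 LTR regions high enough for both lists differed from others by 0.05 in median plastic minus 32 kPa. The bootstrap 95% interval over regions, 0.03 to 0.09, spans the bound of 0.05 and holds no spread between libraries. Surface and read mapping in repeats also stay open, as untested.

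Intergenic regions were 24.4% and 29.7% of the lists (odds ratio 0.765, Fisher's exact test adjusted p = 0.00048). LINE repeats were 0.99% and 1.89% (odds ratio 0.519, Fisher's exact test adjusted p = 0.022). SINE repeats were 0.66% and 1.56% (odds ratio 0.419, Fisher's exact test adjusted p = 0.01).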

How the results depend on the processing

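An FDR under 0.01 left 694 of 2121 regions for 32 kPa, 692 of 2114 for plastic and 193 of 680 in both lists, by construction, and the upper part by level left 1068 and 1068. The promoter odds ratio depended on the setting. For 32 kPa it was 1.03 as reported, 2.20 with an FDR under 0.01, 3.23 against all regions of 32 kPa against plastic and 0.76 at equal level. For plastic it was 0.801 as reported, 1.66 with an FDR under 0.01 and 2.43 against all regions, and 0.706 at equal level. Against all regions the plastic odds ratios of LTR and intergenic regions were 0.923 and 0.671 in place of 1.82 and 1.20. Both settings that raised it compare high listed regions with lower ones, and with an FDR under 0.01 at equal level the values were 0.889 and 0.828. Of regions in 32 kPa against plastic, 55.6% (Wilson 95% interval 55.2 to 56.0) were higher on plastic and 51.9% in the upper part by level; the cause was not tested. Within 2500 bp of a TSS, at a reciprocal overlap of 50% (675 regions), and for all gene lists within 10 kb, in gene bodies or with an FDR under 0.01, no call changed; 0 of 16 lists passed in each. List odds ratios themselves moved: that of YAP/TAZ-TEAD targets for 32 kPa went from 1.36 to 0.413 within 10 kb and 0.878 in gene bodies, and that of integrins from 0.209 to 0.668 in gene bodies. For plastic the transcription factor list went from 0.18 to 0.306 within 10 kb, and the contractile list from 1.22 to 0.98 within 10 kb and 2.5 with an FDR under 0.01. The 0 calls between 32 kPa and plastic held for the upper part by level and for median-centred folds. Both checks reuse the authors' DiffBind p-values and folds, with a lowest p of 0.000997 over 64217 regions. They had little room to call a region and do not show that the surfaces are alike. Named genes in 32 kPa against plastic depended on the region chosen: 9 genes changed sign when the region of highest level replaced that of lowest p, as for Acta2 (0.10 in place of -0.98). Equal-level odds ratios and the background of all regions were chosen after seeing the data. Equal-level odds ratios against other regions can be biased, since listing used a fold that holds the level of the strata. No paired analysis was possible because the tables hold means per culture. For the same reason leaving out libraries, another pseudocount, another count model, a refit and rescaling of the 0.2 kPa tables were not run, and motif alternatives were not run without a genome sequence. Depth per library is unknown, so regions under about 31 reads on the stiffer culture (lowest listed 31.3 and 30.7) cannot be judged against 0.2 kPa.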

Other observations

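The gene families below, the prediction tests for both patterns and their bounds were chosen after the result was seen.

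Among 11 gene families defined by symbol, basement membrane genes were frequent among regions higher on 32 kPa than on 0.2 kPa. They had 10 listed regions nearest to Col4a1, Col4a2, Hspg2, Lama4, Lamb3, Lamc1, Nid1 and Nid2, against 17 other regions (odds ratio 4.15, exact 95% interval 1.69 to 9.61, Fisher's exact test adjusted p = 0.011). The regions nearest Col4a1 and Col4a2 all lay in a single stretch of chromosome 8 (11249712 to 11393522). The test counts them as separate, although regions of a single locus need not be independent. The lead region (chromosome 8, 11382469 to 11382859) lay 69.8 kb upstream of Col4a1, in an intron of a neighbouring transcript. Its level was 5.25 on 0.2 kPa and 6.56 on 32 kPa in the authors' deposited table (fold 1.31, FDR = 0.00218). The Lamc1 promoter rose by 1.13 in the authors' deposited table (FDR = 0.00491). On plastic the same family had 5 regions against 25 (odds ratio 1.5, exact 95% interval 0.449 to 4.01), and no difference between the lists was detected by Fisher's exact test (adjusted p = 0.66). Cytosolic ribosomal protein genes had 13 regions higher on 32 kPa, among them the promoters of Rps19, Rps21, Rpl31 and Rpl28 (odds ratio 2.62, exact 95% interval 1.27 to 5.09, Fisher's exact test adjusted p = 0.047). That call was lost (Fisher's exact test adjusted p = 0.088) with the looser symbol pattern used first, which took in kinase genes and was narrowed after its result was seen. On plastic the ribosomal genes had 8 regions (odds ratio 1.31, Fisher's exact test adjusted p = 0.82), and the lists did not differ detectably (Fisher's exact test adjusted p = 0.7).

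Olfactory and vomeronasal receptor genes, large families of chemosensory receptors, were nearest to 18 regions higher on plastic against 22 other regions (odds ratio 6.19, exact 95% interval 3.13 to 12.1, Fisher's exact test adjusted p = 3.3e-06). Of the 18 regions, 7 lay in annotated repeats. In the 32 kPa list the family had 9 regions against 28 (odds ratio 2.26, exact 95% interval 0.938 to 4.94), and no difference between the lists was detected (odds ratio 0.496, Fisher's exact test adjusted p = 0.32). The region nearest Olfr311 rose in both comparisons, by 1.07 on 32 kPa and 1.12 on plastic in the authors' deposited table. Reads from such similar genes and repeats can be placed wrongly, and no explanation was tested.

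Both tables of 0.2 kPa list regions higher on the stiffer culture alone. A candidate explanation is the authors' filter: no fold was below 1, and 3359 of the 5480 numbered regions of the 32 kPa comparison were missing. Identifiers rose with the p-value, and only 82 of the first 100 were listed. If that order holds for the missing regions, their p-values were no higher than the highest listed one. They were then left out for a reason other than the FDR, such as the size or direction of the fold. How many were higher on 0.2 kPa is unknown. One shift of all regions by the median listed fold of 1.12 would put most high regions at a fold of at least 1. At levels of 7 and more on the stiffer culture, 242 of 1184 regions (20.4%) were listed for 32 kPa and 108 of 1078 (10%) for plastic. These shares argue against a shift of that size at such regions, if they were tested against 0.2 kPa. A smaller shift, biological or from scaling, cannot be told apart from a selective change. At regions listed for plastic the median 32 kPa minus 0.2 kPa was 0.95 (SD 0.26 across regions), within that spread of the median listed fold of 1.12, which the filter itself raises. Those regions were selected on a fold that uses the same 0.2 kPa level, so this value cannot decide about a shift of all regions. For a smaller shift, 80.6% of the regions high enough for both lists have no 0.2 kPa value in the tables used here.

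Only 32.1% of the 32 kPa list overlapped the plastic list, although no region was called between those surfaces. Whether the threshold on the fold accounts for this could not be decided. Of regions in the 32 kPa list alone, 96.3% were at least 0.5 higher on plastic than on 0.2 kPa, and of those in the plastic list alone, 92.9% were at least 0.5 higher on 32 kPa. Both values share the 0.2 kPa level on which regions were selected, which raises them: simulated unchanged cultures with equal error and shared libraries gave 41.3% (95% range 38.6 to 43.9) and 38.1% (35.1 to 40.9). Differences between the surfaces at single regions stay open, as untested with values per library.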
